A study of Anas platyrhynchos with 3 samples.

How the data were processed

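Bill skin of Pekin duck embryos was dissected, frozen, and its RNA isolated with TRIzol; poly(A) RNA was made into strand-specific libraries with the KAPA mRNA Hyper Prep kit, per the labels' protocols. Eggs were kept at 37 °C. The labels give 3 biological replicates of 1 group, numbered 1 to 3 in the sample titles, and each library's values were in a column of their own. Raw counts per gene were deposited by the authors, per the file headers. FPKM values were also deposited by the authors, per the file headers. The submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.36, STAR 2.5.4b, featureCounts of Subread 1.6.2 and edgeR 3.22.3, without a role for each. The genome build and annotation are not given in the sources used here, so no coordinates are printed.

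The deposited FPKM were tested for how they arise from the counts. With edgeR's TMM factors (0.978, 1.008 and 1.014) the gene length implied by count and FPKM was a whole number, within 0.01 bases, for 100% of 14343 genes with reads, against 1.94% without these factors. FPKM thus carry TMM scaling, which makes libraries comparable for most genes. They are also divided by gene length, so genes can be compared within a library as far as the implied lengths hold. Values of near-identical paralogs can be uncertain because reads shared between copies may have been dropped or split. Of 3347 identifiers without a symbol, 2059 were found by gene number in the gene table of the IASCAAS_PekinDuck_T2T assembly and 730 took a symbol from it; 12906 identifiers in all (86.4%) matched. That table was used only for names and for which genes share a chromosome.

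Depth was 32247700, 30630039 and 25268141 counted reads. Genes with fewer than 10 reads are dominated by counting error. Analyses used log2(FPKM + 0.1) and, unless stated, genes with at least 1 FPKM in all 3 libraries. A fold on this scale understates differences of low genes. Tests were run in R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, two-sided at an adjusted p of 0.05. Because there is 1 group, limma's moderated test was applied to the difference between a gene and a reference within each library. The references were CACNA1E for alpha1 calcium channel subunits, PIEZO2 for mechanosensitive candidates and the median gene for members of 30 gene lists. Benjamini-Hochberg adjustment was made over the list alone and over all genes. P-values rest on the spread between these 3 samples, with each gene's variance moderated across all genes kept.

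Under the plan, a reference gene below the minimum allows levels only, which applied to CACNA1E. In ratios to 1 shared gene, limma's prior had unlimited degrees of freedom, so all ratios to a reference had the same SE whatever the gene's own spread. A variance prior from disjoint gene pairs was therefore added after seeing the data. Its p-values are the ones printed for ratios, except where a replicate was left out, for which limma's are given. Gene lists were described by the percentile of their median level, or of their median SD between libraries, among 10000 random lists, matched for the SD on expression in 20 bins. Only list members over the minimum entered these medians. The lists, tests and naming rule were fixed before the data were examined. Named are all measured members of the alpha1 and mechanosensitive lists, the 4 highest members of each other list, the 10 highest symbol-bearing genes, and the 10 with the largest SD of log2 values among those with a mean of at least 10 FPKM. Some results this rule names are not reported here. The lists of mitochondrially encoded and W-chromosome genes had no matching symbol and were not analysed here. Alternatives covered the pseudocount, the minimum, the test, the variance prior, library scaling and leaving out each replicate.

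The tests were tried on counts simulated for 10605 genes from the real means, dispersions and depths, in 20 simulations. Against the library median, 54.1% of genes changed 1.25-fold, 96.2% changed 1.5-fold and 99.9% changed 2-fold were called with the right sign, and 3.45% of unchanged genes were called. Against a gene at the level of PIEZO2, the test with the pair prior called 24.2, 76.8 and 99.7% at the same folds and 1.69% of unchanged genes, with a highest value of 8% in a simulation. The shared-reference test called 4.76% of unchanged genes and up to 19.3% in a simulation. Of 200 simulated lists of 20 genes shifted by 0.4 on the log2 scale in 1 library, 75% varied more than the central 95% of random lists, against 1.5% of unshifted lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.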

Results

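Messenger RNA was measured in bill skin of the Pekin duck (Anas platyrhynchos), a bird that forages by touch and whose bill skin is rich in Pacinian-type and Meissner-type corpuscles, end organs in which lamellar cells surround a mechanosensory nerve ending. The skin came from embryos at embryonic day 24 to 26, which had broken the inner shell membrane 24 to 48 hours before hatching. There were 3 biological replicates of 1 group and no second group, so genes were compared with one another within libraries, and gene groups were compared for how much they differed between libraries. The libraries held 32247700, 30630039 and 25268141 counted reads for replicates 1, 2 and 3. Of 14938 genes, 10605 had at least 1 FPKM (fragments per kilobase of transcript, scaled to the depth of the library) in all 3 libraries, and the median of these genes was 13.3, 13.1 and 13.3 FPKM. Across these genes, log2 values of library pairs correlated with a Pearson r of 0.978, 0.984 and 0.98 and a Spearman rho of 0.975, 0.983 and 0.977 for replicates 1 and 2, 1 and 3, and 2 and 3. Genes are not independent replicates, so these values describe the libraries and carry no p. The median coefficient of variation was 11.7%. All values below are means ± SD with n = 3 unless a library is named.

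Which voltage-gated calcium channels the skin transcribes bears on the study's question of how lamellar cells respond to touch. Transcripts of 8 pore-forming alpha1 subunits were measured. The T-type channel gene CACNA1G was the highest at 2.5 ± 0.235 FPKM, followed by the L-type gene CACNA1C at 1.66 ± 0.492 and the N-type gene CACNA1B at 0.985 ± 0.0756. CACNA1E, which encodes the R-type channel and served as the reference, stood at 0.646 ± 0.110 FPKM, from 115, 150 and 94 reads. CACNA1D, a second L-type gene, was close to it at 0.640 ± 0.164, and CACNA1H, a T-type gene, was at 0.196 ± 0.0190. The skeletal muscle L-type gene CACNA1S was at 0.0508 ± 0.0390 FPKM and the T-type gene CACNA1I at 0.0439 ± 0.00517, the latter from 9 reads in each library. Without replicate 1 the mean of CACNA1S was 0.0283 FPKM. CACNA1A and CACNA1F were not analysed here.

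CACNA1E lay under the minimum of 1 FPKM, so under the plan made before the data were examined only levels were compared. CACNA1G, CACNA1C and CACNA1B exceeded CACNA1E in 3 of 3 libraries, CACNA1H, CACNA1S and CACNA1I lay below it in 3 of 3, and CACNA1D was above it in 2, so that 4 lay above without replicate 1. With a minimum of 0.1 FPKM and a variance prior taken from gene pairs, which was chosen after seeing the data, limma-style moderated tests placed CACNA1G 3.5-fold above CACNA1E (log2 1.81 ± 0.18 SE, adjusted p over the list alone = 0.00027), CACNA1C 2.33-fold above (adjusted p = 0.0034) and CACNA1B 1.46-fold above (adjusted p = 0.015). CACNA1H was 2.5-fold lower than CACNA1E (adjusted p = 0.00048), and CACNA1D did not differ detectably (log2 -0.02 ± 0.16 SE, adjusted p = 0.89). The counts of 3 higher and 1 lower of 5 tested were the same when adjusted over all genes tested. A fold on the log2(FPKM + 0.1) scale understates the difference of genes this low, and a level in whole skin is not a level per lamellar cell.

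**Figure D1:**
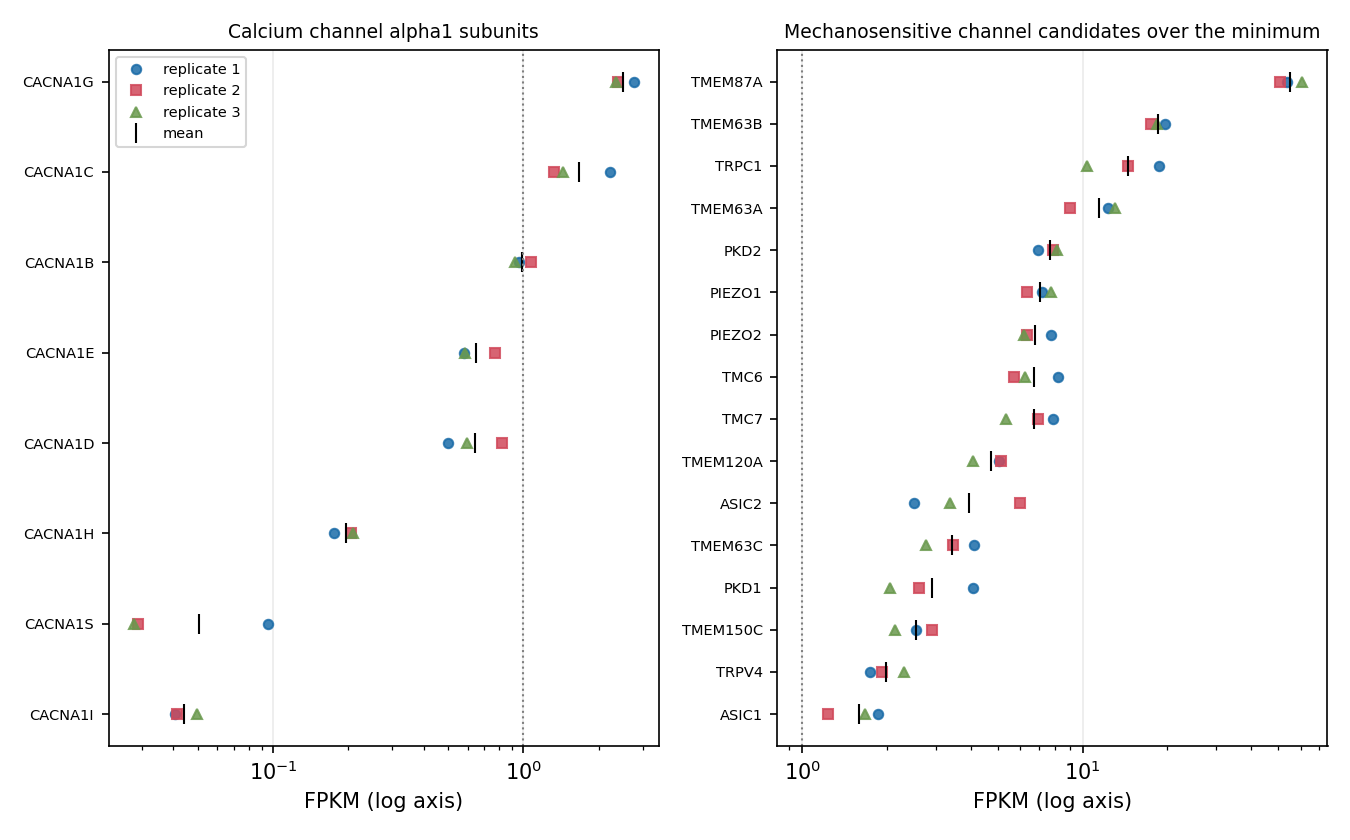
FPKM (log axes) of calcium channel alpha1 subunit genes and of mechanosensitive channel candidates over the minimum in the 3 bill skin libraries, with the mean as a black tick and the 1 FPKM minimum as a dotted line. CACNA1G at 2.5 and TMEM87A at 55.0 FPKM lead the lists.

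Of 11 auxiliary calcium channel subunit genes measured, 7 were under the minimum, 3 lay below the library median gene and 1 was not apart from it. CACNA2D1 was at 3.18 ± 0.651 FPKM, CACNA2D2 at 2.89 ± 0.234 and CACNB2 at 2.48 ± 0.605. The beta subunit gene CACNB4 had the largest SD of log2 values between libraries of the symbol-bearing genes with a mean of at least 10 FPKM, with 90.3, 3.71 and 4.69 FPKM from 12341, 496 and 521 reads. The mean of 32.9 ± 49.7 FPKM therefore rests on replicate 1, and without it CACNB4 was below the median gene (log2 -1.62, limma adjusted p = 0.00018).

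The second comparison set mechanosensitive channel candidates against PIEZO2, the channel of light touch in mammals. PIEZO2 was at 6.75 ± 0.847 FPKM (7.73, 6.33 and 6.20), and its paralog PIEZO1 was at 7.07 ± 0.705. TMEM87A was the highest of the list at 55.0 ± 5.32 FPKM, 8.06-fold above PIEZO2, followed by the osmosensitive channel gene TMEM63B at 18.6 ± 1.09 (2.73-fold), TRPC1 at 14.5 ± 4.16 (2.09-fold) and TMEM63A at 11.5 ± 2.13 (1.68-fold). Lower than PIEZO2 were TMEM120A at 4.73 ± 0.572, ASIC2 at 3.94 ± 1.81, TMEM63C at 3.44 ± 0.670, PKD1 at 2.91 ± 1.04, TMEM150C at 2.54 ± 0.382, TRPV4 at 1.99 ± 0.288 and ASIC1 at 1.59 ± 0.319 FPKM. PKD2 at 7.66 ± 0.616, PIEZO1, TMC6 at 6.70 ± 1.31 and TMC7 at 6.70 ± 1.27 did not differ detectably from PIEZO2. All of these are levels in whole skin and not per cell of any type, so their order does not rank the channels for a role in touch.

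In limma's moderated test, 4 of the 15 candidates tested were higher than PIEZO2 and 7 were lower, adjusted over the list alone, and the counts were the same adjusted over all genes. The reference gene enters every ratio, and that test called up to 19.3% of unchanged genes in a simulation. With the prior from gene pairs, chosen after seeing the data, the same counts of 4 and 7 were obtained, and the adjusted p was 4.4e-06 for TMEM87A, 0.0046 for TMEM63A, 0.018 for TMEM120A, 0.023 for ASIC2 and 2.7e-05 for ASIC1. Without replicate 3 TMEM120A did not pass limma's test (log2 -0.46, adjusted p = 0.0805), nor did ASIC2 without replicate 1 (log2 -0.47, adjusted p = 0.101). The number lower depends on which members the minimum admits and was 18 without one, 15 at 0.1 and 0 at 5 FPKM. Another 11 candidates were under the minimum. TMC5 was at 1.39 ± 0.570 FPKM, KCNK2 at 1.12 ± 0.127, TMC3 at 0.799 ± 0.199, LHFPL5 at 0.570 ± 0.191, TRPC6 at 0.460 ± 0.0540, KCNK10 at 0.423 ± 0.0398, TRPA1 at 0.345 ± 0.307 and STOML3 at 0.226 ± 0.0465, and TRPA1 was at 0.175 FPKM without replicate 2. The hair cell channel genes TMC1 and TMC2 had at most 2 reads in any library, where 3 reads at the lowest depth make 0.0436 and 0.0411 FPKM.

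Other channel families were mostly low. Of 38 voltage-gated potassium channel genes, 32 were under the minimum and 6 lay below the median gene, led by KCNE4 at 2.98 ± 1.11, KCNG1 at 2.57 ± 0.532, KCNAB2 at 2.51 ± 0.640 and KCNE3 at 2.27 ± 1.23 FPKM. All 5 calcium-activated potassium channel genes over the minimum, of 8 measured, were below the median, with KCNMB1 at 7.87 ± 2.55, KCNMB2 at 3.37 ± 0.316, KCNN3 at 2.72 ± 0.242 and KCNU1 at 1.85 ± 0.368. The 7 two-pore and inward-rectifier genes tested, of 23, were also below it, with KCNJ15 at 9.55 ± 1.51, KCNK1 at 8.89 ± 0.904, KCNJ8 at 3.70 ± 0.315 and KCNJ10 at 3.40 ± 0.907. Among 13 sodium channel genes, the epithelial subunit SCNN1A at 23.9 ± 3.14 FPKM was above the median and SCNN1B at 12.7 ± 1.27 was not apart from it, while 4 were below, including SCN2B at 5.66 ± 1.61 and SCNN1G at 5.33 ± 0.453. Of 21 TRP channel genes, 6 were tested. TRPC1 and TRPM7, the latter at 13.9 ± 2.03, were not apart from the median, and 4 were below, including TRPV3 at 9.49 ± 2.71. Among 20 HCN and chloride channel genes, the volume-regulated subunit LRRC8D at 41.2 ± 11.7 was above the median and 6 were below, while ANO6 at 15.7 ± 4.09, LRRC8A at 13.6 ± 2.62 and CLCN7 at 13.3 ± 1.37 were not apart.

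Neuronal signalling genes were also mostly low. Of 42 glutamate, GABA and purinergic genes, 36 were under the minimum, 5 were below the median and 1 was above it, the ATP and ADP receptor gene P2RY1 at 38.6 ± 0.561 FPKM. P2RX1 was at 8.66 ± 2.92, P2RX4 at 7.09 ± 0.378 and GRIA3 at 3.60 ± 1.07. Of 26 vesicle release genes, the widely expressed VAMP3 at 62.9 ± 8.89 and SNAP23 at 25.4 ± 1.02 were above the median, 8 were below, including DNM1 at 7.71 ± 0.347 and VAMP1 at 6.03 ± 2.79, and 16 were under the minimum. The median levels of the auxiliary calcium, voltage-gated, calcium-activated and two-pore potassium channel lists and of the vesicle release list lay at the 1.06th, 0.09th, 0.8th, 0.7th and 0.94th percentile of random lists of the same size. These 5 lists lay below the central 95% of random lists, against 8 without a minimum, 12 at 0.1 and 1 at 5 FPKM. Only members over the minimum entered these percentiles, so they do not rank the lists over all members. Over all measured members, the glutamate, GABA and purinergic list had a median of 0.112 FPKM and the TRP list 0.345. Their percentiles, from members over the minimum, were 4.23 and 21.6. Without a minimum the median gene is lower, and in limma's test KCNJ15 (log2 0.46, adjusted p = 0.0174) and KCNK1 (0.37, adjusted p = 0.0147) were above it. KCNMB1 (log2 0.15, adjusted p = 0.488), TRPV3 (0.43, 0.0822), P2RX1 (0.27, 0.344), P2RX4 (0.05, 0.536) and DNM1 (0.17, 0.0832) were then not apart from it. TRPV3, at log2 -0.51 with all libraries, was also not apart from the median without replicate 1 (log2 -0.35, limma adjusted p = 0.174) or 2 (-0.41, 0.0875), and ANO6, at 0.21 with all, was above it without replicate 2 (0.42, 0.0255).

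Among the cell type lists, epidermal and dermal genes had the highest medians. Of 23 keratinocyte genes, 18 were above the median gene and 4 below it, led by SFN at 1810 ± 131, the adhesion genes PERP at 1024 ± 157 and DSP at 744 ± 133, and JUP at 567 ± 59.6 FPKM. Of 22 dermal fibroblast genes, 20 were above it, with the matrix genes SPARC at 1417 ± 439, COL1A2 at 1087 ± 430, DCN at 940 ± 346 and POSTN at 466 ± 123. Of 19 Schwann and lamellar cell genes, 18 passed the minimum, 8 were above the median and 7 below, with the myelin genes PMP22 at 303 ± 122 and MBP at 229 ± 90.6, GPM6B at 42.0 ± 5.76 and TFAP2A, also an epidermal regulator, at 37.3 ± 6.32. Among 14 Merkel cell genes, the granule genes CHGB at 143 ± 44.3 and CHGA at 32.8 ± 18.2 were above the median, 4 were below, including POU4F3 at 5.05 ± 1.73, and SOX2 at 11.3 ± 2.13 was not apart. The other 7 Merkel cell genes were under the minimum. Among 14 sensory neuron genes, TAC1 at 63.9 ± 22.1 and UCHL1 at 28.1 ± 8.0 were above the median, MAPT at 13.5 ± 5.80 was not apart, and 4 were below, including ADCYAP1 at 5.59 ± 1.16. The other 7 sensory neuron genes were under the minimum, among them SNAP25 at 0.692 ± 0.392 and STMN2 at 0.496 ± 0.0563 FPKM.

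Markers of further cell types had lower list medians than the keratinocyte and fibroblast lists. Of 14 endothelial genes tested, PECAM1 at 44.5 ± 6.72 and EGFL7 at 17.5 ± 2.69 were above the median and 7 were below, with CDH5 at 15.1 ± 1.79 and CLDN5 at 12.6 ± 1.69 not apart. Of 9 smooth muscle and pericyte genes, 4 were above and 3 below, with ACTA2 at 70.5 ± 8.15, ACTG2 at 61.7 ± 18.7, MYLK at 20.4 ± 3.93 and MYH11 at 18 ± 3.82. Of 21 skeletal muscle genes, 16 were under the minimum and TPM2 at 109 ± 34.4 was above the median, while MYL1 at 31.4 ± 20.8 and ACTA1 at 11.1 ± 3.87 were not apart and TNNC2 at 4.06 ± 0.856 was below. Of 15 cartilage and bone genes tested, SPP1 at 70.8 ± 48.9 and COL11A1 at 30.0 ± 8.57 were above and 10 below, with HAPLN1 at 14.5 ± 2.39 and IBSP at 11.8 ± 11.1 not apart. Of 6 adipocyte genes tested, 4 were above, SCD at 69.7 ± 0.5, ADIPOQ at 51.3 ± 4.99, CEBPA at 46.4 ± 5.44 and DGAT2 at 25.6 ± 7.55, and 2 were below, LPL at 7.90 ± 0.546 and PPARG at 2.20 ± 0.292. LEPR, PLIN1 and CIDEC were under the minimum, and the last 5 were named after their values were seen. The 3 melanocyte genes tested of 11 were below, MITF at 6.62 ± 0.472, KIT at 6.40 ± 0.654 and SLC24A5 at 2.77 ± 0.2, with OCA2 under the minimum at 0.358 ± 0.116. The 5 leukocyte genes tested of 23 were below, with CD74 at 8.52 ± 5.17, CD3D at 6.15 ± 0.474, LAPTM5 at 4.13 ± 1.02 and BLNK at 3.78 ± 1.19. Of 4 erythroid genes, TFRC at 13.7 ± 0.552 was not apart, SPTB at 1.20 ± 0.159 was below, and RHAG and EPB42 were under the minimum. Calls in limma's test that changed when 1 library was left out included those of EGFL7, MYH11 and CD74, at log2 0.39, 0.42 and -0.79 with all libraries. EGFL7 did not pass without replicate 1 (log2 0.41, adjusted p = 0.0742) or 2 (0.29, 0.069), MYH11 without replicate 2 (0.28, 0.0796) or 3 (0.44, 0.0727), and CD74 without replicate 1 (-0.52, 0.195) or 3 (-0.55, 0.144). SOX2 was below the median without replicate 1 (log2 -0.36, adjusted p = 0.0399), MYL1 above it without replicate 3 (1.6, 0.00043) and IBSP below it without replicate 2 (-1.28, 8.3e-05). Without replicate 2 the means of SPP1, IBSP and CD74 were 42.8, 5.37 and 5.53 FPKM, and without replicate 1 that of MYL1 was 20.6. At a minimum of 5 FPKM, EGFL7 (log2 -0.21, adjusted p = 0.0996) and MYH11 (-0.18, 0.243) were not apart from the median gene, nor was CD74 without a minimum (0.15, 0.68).

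**Figure D2:**
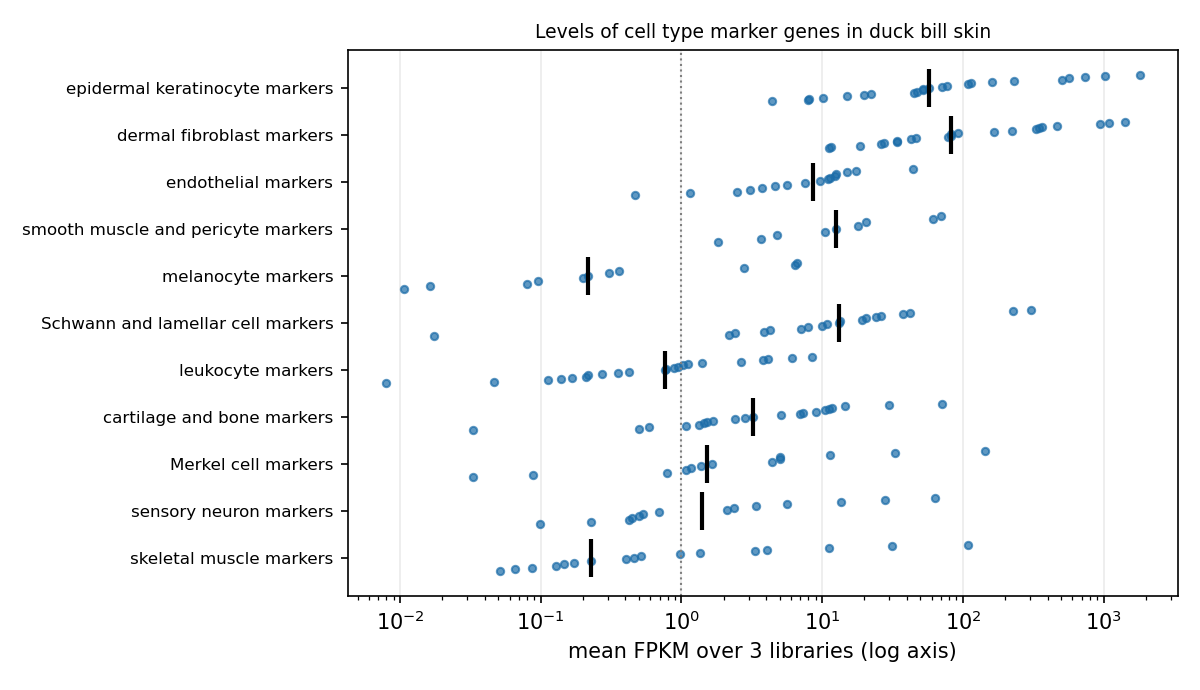
Mean FPKM over the 3 bill skin libraries (log axis) of each measured marker gene of 11 cell types, 1 point per gene, with the median of the list as a black tick and the 1 FPKM minimum as a dotted line. Genes with no reads are not drawn. The keratinocyte and fibroblast lists have medians of 57.7 and 82 FPKM.

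All 44 ribosomal protein genes were above the median, with RPS7 at 3416 ± 334, RPS3A at 3358 ± 441 and RPS12 at 3330 ± 497 FPKM. Of 25 cell division genes tested, 15 were above and 4 below, led by CDK1 at 77.4 ± 14.3, PCNA at 67.7 ± 14.1, RRM2 at 52.9 ± 7.04 and CCNB2 at 40.7 ± 4.57. Of 18 hypoxia and glycolysis genes, 15 were above and 2 below, with ENO1 at 1069 ± 160, GAPDH at 1059 ± 23.8, PGAM1 at 424 ± 22.7 and LDHB at 241 ± 10.6. Of 21 immediate early and stress genes tested, 13 were above and 4 below, with the heat shock genes HSP90AA1 at 536 ± 143, HSPA2 at 305 ± 72.4 and HSPA8 at 221 ± 45.2, and DDIT4 at 187 ± 35.3. In limma's test against the library median, 4636 of 10605 genes were above and 4619 below over all genes tested, and the counts per list are those adjusted over the list alone. Adjusted over all genes tested they were the same, except for skeletal muscle with 2 above. The highest gene of all, at 20799 ± 3312 FPKM, had no symbol. The highest symbol-bearing gene was the elongation factor EEF1A1 at 9538 ± 1595 FPKM, at rank 5 of all genes. The next 9 symbol-bearing genes, from rank 10 on, encoded ribosomal proteins, among them RPS15A at 3038 ± 256, RPS24 at 2911 ± 310, RPL23A at 2848 ± 313, RPL37 at 2678 ± 819 and RPL7A at 2670 ± 268. The 20 highest genes, with or without a symbol, took 22.8, 19.3 and 18.8% of summed FPKM.

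Relative to random lists matched on expression, the libraries differed most in fibroblast genes. The median deviation of the fibroblast genes from their own log2 mean was -0.26, 0.46 and -0.22 in replicates 1, 2 and 3, and 20 of 22 were highest in replicate 2, as with DCN at 673, 1330 and 817 FPKM. Keratinocyte genes deviated by 0.09, -0.18 and 0.12, and 19 of 23 were lowest in replicate 2. The median SD of the fibroblast list was 0.41 on the log2 scale, above all random lists matched on expression (100th percentile). The lists for cartilage and bone (0.39, 99.98th percentile), stress genes (0.26, 99.86th), Merkel cells (0.46, 99.82nd), sensory neurons (0.45, 99.78th), skeletal muscle (0.43, 99.46th) and Schwann and lamellar cells (0.25, 98.44th) also lay above the central 95% of random lists. Part of this rested on single libraries. Without replicate 2 the fibroblast list was at the 90.37th percentile, the Schwann and lamellar list at the 1.68th and the stress genes at the 91.12th, and the last were at the 90.18th without replicate 1. Without replicate 3 the sensory neuron list was at the 66.1st and the skeletal muscle list at the 93.16th percentile. The keratinocyte list rose to the 99.12th without replicate 1 and the 98.76th without replicate 3, smooth muscle to the 99.77th without replicate 3, and ribosomal protein genes to the 99.99th without replicate 2. Deviations of the Schwann and lamellar list were -0.06, 0.19 and -0.11. Ribosomal protein genes deviated by 0.16, -0.02 and -0.15 and were highest in replicate 1 for 38 of 44.

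Besides CACNB4, the symbol-bearing genes with the largest SD of log2 values between libraries, among those with a mean of at least 10 FPKM, were the neuropeptide gene UCN2 (4.82, 21.8 and 37.7 FPKM), the matricellular gene NOV (104, 492 and 111), the bone sialoprotein gene IBSP (4.85, 24.5 and 5.90), MYL1 (53.0, 29.7 and 11.5), CHRNA10 (16.2, 25.4 and 5.64), STC2 (6.99, 29.1 and 9.09), TNFAIP6 (6.13, 26.9 and 13.0), GZMM (3.92, 16.4 and 11.1) and AKR7A2 (101, 82.8 and 27.1). Genes are not replicates and no sample was set against the others in a test, so these percentiles and values describe the 3 libraries only.

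**Figure D3:**
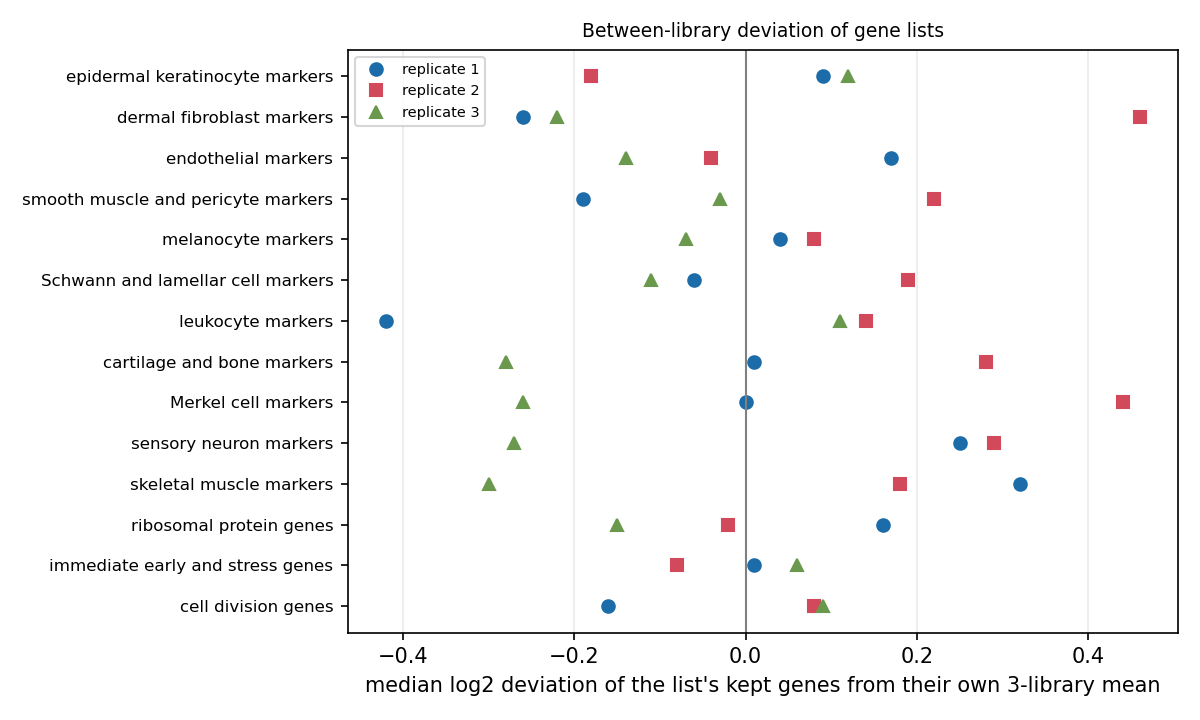
Median log2 deviation of each list's genes over the minimum from their own mean of 3 libraries, 1 symbol per library. The fibroblast list stands at 0.46 in replicate 2 and the keratinocyte list at -0.18.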

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

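The gene pair prior, size-factor (RLE) scaling, and the pair prior, pseudocount 1 and 1.5-fold test at a minimum of 0.1 FPKM were chosen after seeing the data; the other alternatives were planned. Most results kept their direction and side of the threshold: of the values for single genes and lists, 2284 were the same, 147 moved, 55 passed the threshold only under the alternative, 53 lost it and 14 reversed. Most shifts came from the minimum, which decides which genes are tested and where the median gene lies. Members of the alpha1 list below CACNA1E numbered 3 as reported and 1 at a minimum of 0.1 FPKM, also with the pair prior, with pseudocount 1 and with the 1.5-fold test, since CACNA1S and CACNA1I fall under it. Members below PIEZO2 numbered 7, and 18, 15 and 0 with no minimum, 0.1 and 5 FPKM. List members below the median gene numbered 124, and 311, 227 and 76, and lists in the lower tail of level 5, and 8, 12 and 1. The lowest Pearson r was 0.978, and 0.984 with no minimum. Reversed because the median gene moved were, at 5 FPKM, TMEM63B (-0.12), EGFL7 (-0.21) and MYH11 (-0.18), and with no minimum PKD2 (0.16), PIEZO1 (0.04), KCNMB1 (0.15), KCNJ15 (0.46), KCNK1 (0.37), TRPV3 (0.43), P2RX1 (0.27), P2RX4 (0.05), DNM1 (0.17) and CD74 (0.15), in log2 against the median, of which KCNJ15 and KCNK1 passed limma's test under that setting. Leaving out each replicate gave 3 to 4 alpha1 members above CACNA1E and 3 below, 4 above PIEZO2 and 6 to 8 below, 155 to 156 list members above and 120 to 129 below the median, 5 lists in the upper and 5 to 7 in the lower tail of level, 5 to 7 variable lists, 10702 to 10711 genes kept and 19.0 to 21.1% of FPKM in the 20 highest genes. The 1.5-fold test left 3 higher and 5 lower than PIEZO2. Each scaling gave 7 variable lists. The FPKM already carry TMM scaling, so applying TMM factors to them could change little. The 26 values under that setting are among the 2284 that were the same. Because CACNA1E is under the minimum, the planned pseudocounts, the minimum of 5 FPKM, the 1.5-fold test and the trended prior gave no test for the alpha1 list. No paired analysis was possible because there is 1 group. Depth limits genes with fewer than 10 reads, among them CACNA1I, TMC1 and TMC2.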

Other observations

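Genes of 3 lists added after the main results had been seen describe further signalling in the skin, as mean ± SD FPKM with n = 3. Of 35 genes that pattern skin appendages, 33 were measured and 31 had at least 1 FPKM in all libraries. CTNNB1 was at 246 ± 12.6 FPKM, the growth factor receptor genes FGFR3 and FGFR2 at 59.7 ± 9.87 and 55.9 ± 7.49, and the ligand genes WNT5A, WNT10A, BMP4 and BMP7 at 45.0 ± 1.95, 30.9 ± 1.52, 27.1 ± 7.77 and 25.1 ± 3.20. SHH, by contrast, was at 0.0948 ± 0.0561 FPKM, or 0.0624 without replicate 2, while the genes of its receptor and effector, PTCH1 and GLI1, were at 2.82 ± 0.0766 and 3.66 ± 0.0832. MSX1 stood at 14.1, 29.8 and 19.3 FPKM in replicates 1, 2 and 3.

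Of 25 neurotrophic factor and receptor genes, 21 were measured and 15 passed the minimum. The receptor genes NGFR and GFRA2 were at 13.2 ± 1.26 and 11.3 ± 2.65 FPKM and NTRK3 and NTRK2 at 3.41 ± 0.601 and 2.12 ± 0.583. Among ligand genes, NTF3 was at 1.94 ± 0.391, BDNF at 1.38 ± 0.211, NRTN at 1.29 ± 0.0991 and GDNF at 1.02 ± 0.308. Of 15 gap junction and pannexin genes, 14 were measured and 9 passed, and GJA1 at 1157, 772 and 1264 FPKM was far above GJB2 at 66.8 ± 6.53, GJC1 at 7.81 ± 0.824 and PANX1 at 7.54 ± 2.24.

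The tests below on the epidermal share, embryo sex, the dermal share and the count of muscle genes were chosen after the result was seen, and those on length, Z-linked members and genes at 8 times both other libraries before. The design gives 1 group, so no biological explanation from the design was tested.

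Fibroblast genes were highest in replicate 2 (median log2 deviation 0.46) and keratinocyte genes lowest (-0.18). A smaller epidermal share of the skin piece would raise every other cell type alike only if the rest of the piece kept its mix of cells. The fibroblast median exceeded the endothelial one by 0.50 (95% bootstrap interval over genes of this 1 library 0.24 to 0.57). The comparison with the endothelial list was chosen after the result was seen, and the mix of the rest is not known. The gap therefore does not decide on the epidermal share in replicate 2. The medians of other lists there were 0.44 for Merkel cells, 0.29 for sensory neurons, 0.28 for cartilage and bone, 0.22 for smooth muscle, 0.19 for Schwann and lamellar cells, 0.18 for skeletal muscle, 0.14 for leukocytes, 0.08 for melanocytes, -0.04 for endothelium and -0.08 for adipocytes. Length and expression bias is argued against by a percentile of 100 among 10000 lists matched on both, whose medians lay between -0.09 and 0.06, and Z linkage by 0 of 22 list members on that chromosome. A change within the dermal fibroblasts, or a smaller epidermal share, alone or together with a change in vessels, may remain, and these were not separated.

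The median deviation of 444 genes on the chromosome named Z in the IASCAAS_PekinDuck_T2T assembly was -0.11, 0.18 and -0.09 in replicates 1, 2 and 3, with an interval of 0.15 to 0.22 for replicate 2, while the 29 other chromosomes with at least 50 genes had medians from -0.042 to 0.021 there. The 23 genes on W with at least 100 reads in all held 12859, 1699 and 10450 reads, and 13 of them had under 5% of the FPKM of either other library in replicate 2. Length is argued against by a percentile of 100 for the Z median among 2000 lists matched on length and expression, and the dermal share is argued against for the 13 W genes, since no keratinocyte gene was under 62.8% of another library in replicate 2. It is also argued against for the Z-linked ribosomal protein genes RPL37, RPS6 and RPS23, named after their values were seen, whose mean log2 deviation of 0.53 (SD 0.09) in replicate 2 exceeded that of the other 41 (-0.02, SD 0.06) by 0.56, and stays open for the other Z genes, on which no test bears. As a hypothesis, the embryos may have differed in sex, since female birds carry a W and a single Z. The Z median of 0.18 is the pattern itself, so it is no test of this. Z genes were 1.22-fold and 1.2-fold higher in replicate 2 than in replicates 1 and 3. No fold was set as the one that a difference in sex would give, so these folds argue neither for nor against it. Sex is not given in the sources used here.

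A drop of at least 20-fold below both other libraries, among genes with at least 1 FPKM in those, occurred for 6, 31 and 2 genes in replicates 1, 2 and 3. Of the 31, 14 were on W, 0 were on another named chromosome and 17 had no match in the gene table.

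CACNB4 had 24.4 and 19.2 times the FPKM in replicate 1 that it had in replicates 2 and 3. Whether cells of another type brought it could not be decided: 8 genes with at least 1 FPKM were at 8 times or more both other libraries, under the 10 set beforehand as the bound that excludes it, but that bound passes over genes below 1 FPKM. These 8 include CACNB4 itself. They also include TNNT3 of the skeletal muscle list, named after its values were seen, at 3.95, 0 and 0.0843 FPKM in replicates 1, 2 and 3. Of 17 skeletal muscle genes with reads, 14 were highest in replicate 1 and 7 were at 3 times or more both other libraries. Of these 7, 4 were under 1 FPKM in replicate 1. Examples, named after their values were seen, were TTN (577, 30 and 32 reads, mean 0.0661 FPKM) and ACTN2 (305, 48 and 27 reads, mean 0.978 FPKM). The 5 muscle list members over the minimum deviated by 0.32 in replicate 1 (99.94th percentile) and by 0.18 in replicate 2 (94.57th). The more abundant muscle genes differed less, with MYL1 at 53.0, 29.7 and 11.5 FPKM and ACTA1 at 13.8, 12.9 and 6.67, against 90.3 for CACNB4. Muscle or another cell type may have been the source, which stays open, and where along CACNB4 the reads lie was not analysed here.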
